A study of Caenorhabditis elegans with 29 samples.

How the data were processed

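Gene expression was measured by RNA sequencing in 29 libraries of dissected gonads: 21 of the unc-119::gfp reporter strain in 7 groups of stage and RNAi, and 8 of wild type, glh-1(gk100) and pgl-1(ct131) him-3(e1147). Per the labels, total RNA was depleted of ribosomal RNA, libraries were made with a kit that does not mark the strand, and HiSeq machines of 3 models were used, so reads of overlapping genes on opposite strands cannot be told from each other. The labels do not say that replicates were separate cultures, and a p-value then measures the spread between these samples. TopHat2 and DESeq2 were used by the authors, per the submitters' processing notes; their versions, the genome build, the annotation and the read counter are not given in the sources used here.

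A table of 45627 genes was used. Per the file headers it holds, for each of 7 comparisons, a deposited log2 fold change, a deposited p-value with Benjamini-Hochberg (BH) adjustment over the genes given a value, and a deposited mean expression, which is the mean of normalized read counts over the libraries compared. The deposited signal values are read count averages per group, per the file headers; from the values, the authors divided gene read counts by a factor per library and averaged them, for the 7 RNAi groups and the 3 mutant groups apart. The deposited fold changes of low genes, and of some at higher levels such as pgl-1 and him-3 at L4, are smaller in size than the ratio of the averages. Shrunken estimates have this trait, so the deposited fold changes are no measure of the full size of a change. In 5 further columns 0 or 1 marks the authors' gene categories (ubiquitous, germline-enriched, germline-specific, soma-specific and sperm), a deposited label of membership with no unit; how they were chosen is not given in the sources used here, and they are not independent evidence. Names come from the table, with 6 replaced from the reference annotation (WBcel235, release 115) where the table holds a number in place of a name; 42420 identifiers matched that annotation, which served for names and gene neighbours.

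The deposited fold changes and adjusted p (threshold 0.05) were taken as the results of the 7 comparisons. Groups were deposited pooled, as averages with no error. Because an average of 2 or 3 whole read numbers over fixed factors leaves few possible sets, the whole reads of each library were worked out from the averages, and each SD and n in the text comes from these recovered values. Recovered libraries are named a, b and c by falling depth, since their replicate numbers are unknown. Genes with a single solution gave back the deposited mean expression, which was not used to find them, within a relative 1e-06 for 100 percent of genes checked (15111 to 21707 genes per comparison, with the scale of each library fitted on other genes). For the 0 to 150 genes per group with several solutions, the mean expression was used to choose among them. In simulated groups 99.8, 99.7 and 100 percent of genes were recovered and 0 wrongly. This step was chosen after the table was seen. Depth ran from 1027223 to 9079321 reads per library, where a gene at 100 reads has a counting error of about 10 percent and a gene absent from the shallowest library can still be present at a low level.

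Comparisons without deposited columns (Day 1 against L4 control, Day 2 against Day 1 control, and the 2 differences of the RNAi effect) were fitted to the recovered reads with limma 3.58.1 in R 4.3.3, all groups of a part in the same fit, BH threshold 0.05, genes with a group mean of at least 1 normalized read (23460 in the RNAi part and 15189 in the mutant part). The limma-trend fit of log2 values with a pseudocount of 1, planned before the data were examined, failed its test on simulated data: 48.7, 57.6, 32.1 and 41.3 percent of its calls were false for L4 RNAi, Day 1 RNAi, Day 1 against L4 control and the Day 1 to L4 difference. Of 6 fits tried, limma voom was taken in its place after the data were seen. With voom, false calls were 21.0 percent for L4 RNAi, 15.1 percent for Day 2 against Day 1 control and 1.32 to 9.05 percent elsewhere, so calls at L4 are to be read with care; 88 to 100 percent of 4-fold changes and 29 to 95 percent of 2-fold changes were found. The same fit was run for the 7 deposited comparisons as an addition, for the tests that need libraries.

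In total 22 gene lists were fixed before the data were examined: RNAi targets, germ granule and small RNA pathway, spermatogenesis, oogenesis and maternal, meiotic prophase, germline stem cell and proliferation, neuronal, neuropeptide, muscle, intestine, hypodermis and seam, cuticle collagens, somatic gonad, developmental transcription factors, major sperm proteins, major sperm protein domain, histones, ribosomal proteins, heat shock and stress, apoptosis and DNA damage response, germline chromatin regulators, and X chromosome dosage compensation. Lists share members (31 of 53 spermatogenesis genes are in the authors' sperm category), and genes of the major sperm protein, histone, collagen, vitellogenin, ssq, nspd and prg families are near copies whose reads cannot be fully assigned. Each list was tested by a two-sided Fisher exact test of its calls in each direction against the other genes tested, BH over lists and directions within a comparison, with the authors' categories adjusted apart; a test can pass because a list holds fewer calls than other genes. In simulations 4.6 percent of 500 random lists and 100 percent of 200 enriched lists had p below 0.05. Fisher tests take genes as independent, so camera (limma) was run on the recovered reads with a correlation of 0.01 and with an estimated correlation, and its adjusted p from the latter is given beside list calls. For lists, counts adjusted over the list alone are BH over the members only.

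Named genes were chosen by a rule fixed before the data were examined: (a) unc-119 and the 4 targets; (b) up to 6 largest rises and 6 largest falls among called genes with a gene name, above-median abundance and no overlap of the libraries of the groups, which happens by chance for 10 percent of genes with 3 against 3 libraries; (c) for each list with at least 3 calls the 2 with the smallest p not under (b). Both genes called between Day 2 and Day 1 controls, hil-4 and T12F5.2 were named after their values were seen. Overlaps of calls were set beside the number shared by independent lists. Real groups were set among splits of the same libraries, with the real split counted: all 10 for 2 groups of 3, and 100 for differences of effects. The others of these 100 were drawn and regrouped the stages within control and within RNAi libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 did the rest. Alternatives were an adjusted p of 0.01, a fold of at least 2, other pseudocounts, no filter, another scaling, the compared groups alone, weights, other list tests, and leaving out each library; Day 1 libraries c left out together, the weights and centring on the authors' ubiquitous genes were added after the data were seen.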

Results

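RNA was sequenced from gonads dissected from Caenorhabditis elegans grown at 24 °C, in 29 libraries that fall into 10 groups. The RNAi part (21 libraries, 3 in each of 7 groups) used a strain with an unc-119::gfp reporter, which lights up neurons in an intact worm. Worms took up empty vector bacteria or bacteria making double-stranded RNA against 4 genes (glh-1, glh-4, pgl-1 and pgl-3) that encode components of P granules, the RNA and protein granules of germ cells. Gonads of the next generation were taken at the fourth larval stage (L4) and 1 or 2 days later (Day 1, Day 2), and Day 2 RNAi gonads were kept apart by whether the reporter was visible in them (GFP-positive or GFP-negative). The mutant part held Day 1 wild-type (n = 3), glh-1(gk100) (n = 2) and pgl-1(ct131) him-3(e1147) (n = 3) gonads. Gonads per library numbered 75 to 100 in controls and 125 to 150 in RNAi groups. For L4 RNAi gonads, above 80 percent of sibling adults were sterile. Adult RNAi gonads came from sterile worms, and stunted ones were taken whole while large ones and controls were cut at the bend.

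Reads on genes per library, worked out from the deposited group averages and listed as libraries a, b and c of each group by falling depth, were 3012339, 1465248 and 1207471 for L4 control; 3749155, 3150402 and 1555591 for L4 RNAi; 6146118, 4233237 and 1221224 for Day 1 control. They were 3745929, 2933959 and 1027223 for Day 1 RNAi; 9039174, 7702008 and 6705977 for Day 2 control; 6487330, 6288064 and 4633844 for Day 2 GFP-negative. For Day 2 GFP-positive they were 9079321, 6842801 and 5613524; for wild type 4303736, 3269234 and 1158248; for glh-1 3980657 and 1416931; for pgl-1 4416849, 2866889 and 1697197. Levels below are normalized reads, as mean ± SD over these libraries, and the RNAi and mutant parts were normalized apart. At an even depth of 1027223 reads, libraries c of Day 1 control and Day 1 RNAi were expected to show 16769 and 19256 genes, against 9854 and 10558 or 13656 and 14361 in the other libraries of their groups. Day 2 control libraries a, b and c were expected to show 9708, 9766 and 10249 genes at that depth. Day 2 GFP-negative libraries came to 14617.5, 15094 and 14499, and GFP-positive ones to 16124, 15693.5 and 15731.

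The question put first was whether the targeted transcripts fell. PGL-1 and PGL-3 are RGG-box proteins that form the body of P granules, and GLH-1 and GLH-4 are RNA helicases related to Vasa. At L4, pgl-1 stood at 63.03 ± 85.2 normalized reads against 2389.97 ± 227 in controls, and pgl-3 at 87.98 ± 59.6 against 1084 ± 115 (SD, n = 3 each). Levels of glh-1 were 204 ± 201 against 2323 ± 407, and those of glh-4 106 ± 69.8 against 972 ± 74.5 (SD, n = 3 each). The L4 RNAi libraries differed in depth of knockdown: pgl-1 was at 161 in library b, against 18.9 and 8.90 in the other 2. At Day 1, pgl-1 was at 26.5 ± 9.22 against 1959 ± 64.4 and glh-1 at 138 ± 56.2 against 1501 ± 20.9 (SD, n = 3). Day 2 levels of pgl-1 were 14.3 ± 3.50002 in GFP-negative and 27.03 ± 33.8 in GFP-positive gonads, against 2034 ± 28.2 in controls (SD, n = 3). Each target fell in each comparison of RNAi with control gonads in the authors' deposited table. Log2 fold changes there ran from −1.44 (pgl-1 at L4) to −7.34 (pgl-1 in Day 2 GFP-negative gonads) in the authors' deposited table, with a BH-adjusted p of at most 0.00681. The value of −1.44 is smaller in size than the averages of 63.03 and 2389.97 give, so it does not mark pgl-1 at L4 as the weakest knockdown. In the pgl-1 mutant, pgl-1 was at 187 ± 105 against 1751 ± 615 in wild type (SD, n = 3). In the glh-1 mutant, glh-1 was at 2126 ± 261 (SD, n = 2) against 1425 ± 691 (SD, n = 3). That change did not pass in the authors' deposited table (log2 fold change 0.54, BH-adjusted p = 0.32). Reads outside the deleted part of glh-1 check nothing about the label.

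**Figure D1:**
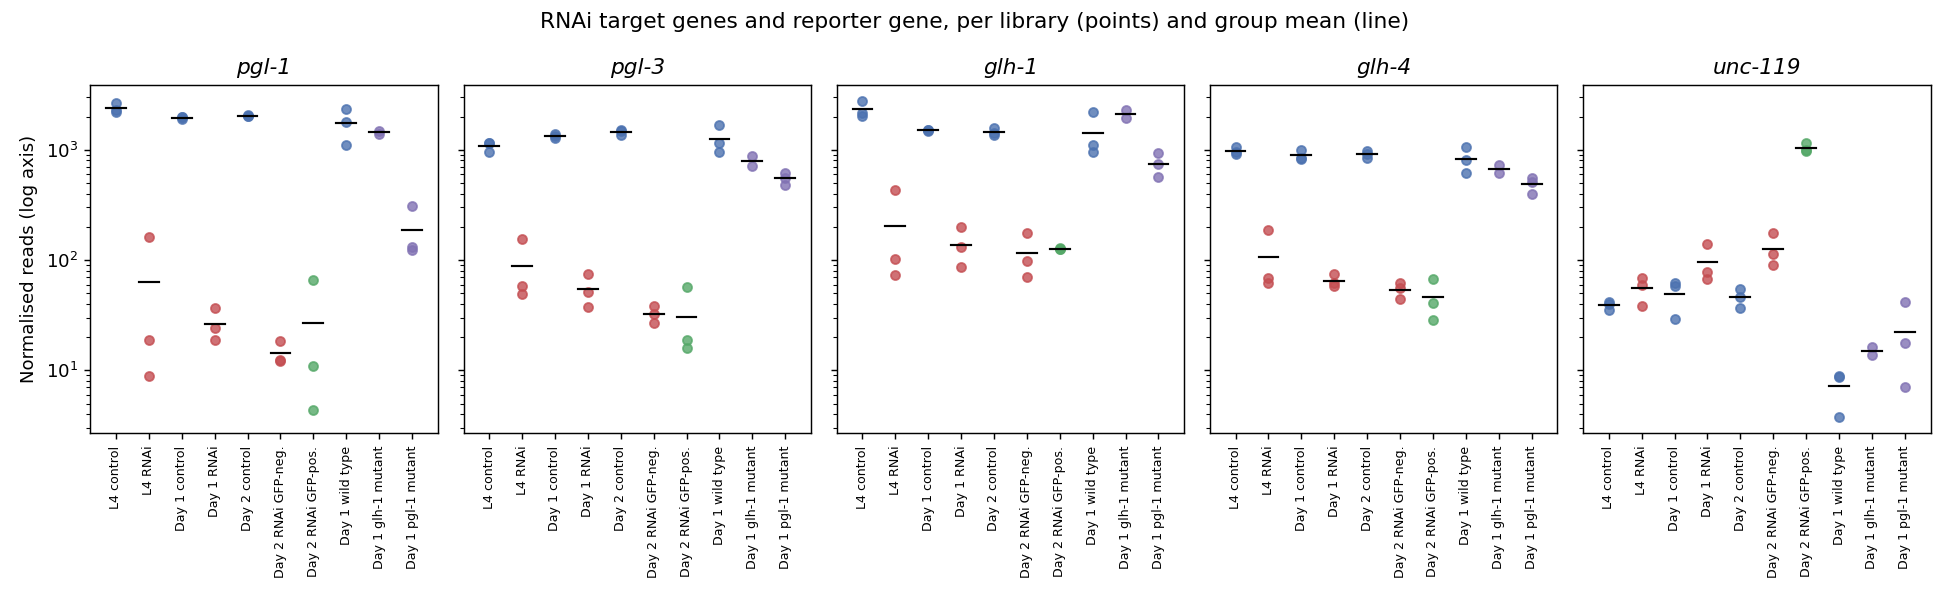
Normalized reads (log axis) of the 4 RNAi targets and unc-119 in 10 groups of gonads; points are libraries and lines are group means (n = 3, glh-1 mutant n = 2), with RNAi and mutant parts normalized apart. The mean of pgl-1 went from 2034 in Day 2 controls to 14.3 in Day 2 GFP-negative RNAi gonads, and unc-119 stood at 1035 in GFP-positive gonads.

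The L4 comparison asks which transcripts change in the larval gonad, at a stage when sterility could not yet be seen. Few genes beside the targets were called in the authors' deposited table. Among them, him-3, for a protein of the meiotic chromosome axis, was at 48.9 ± 25.8 against 478 ± 50.8, and glh-2, a helicase gene of the glh-1 family, at 111 ± 39.3 against 515 ± 85.1 (SD, n = 3 each). The gene hacd-1, for a hydroxyacyl-CoA dehydrogenase, was at 42.7 ± 12.9 against 195 ± 67.4 (SD, n = 3 each). In the authors' deposited table these fell by log2 fold changes of −2.17, −1.65 and −1.52 (BH-adjusted p = 2.03e-08, 1.61e-05 and 0.000729). Of the genes taken by the naming rule, the largest rise was that of glit-1, for a gliotactin-like protein, at 471 ± 182 against 67.5 ± 8.52 (SD, n = 3 each). Hexosaminidase gene hex-1 was at 169 ± 21.2 against 72.7 ± 9.76 (SD, n = 3 each). Log2 fold changes of these 2 genes were 1.97 and 1.02 in the authors' deposited table (BH-adjusted p = 3.81e-07 and 0.0425). The authors' deposited table held 13 rises and 9 falls among 10924 genes with an adjusted p. The falls were the 4 targets, him-3, glh-2, hacd-1, hil-4 (a linker histone gene) and T12F5.2. The last 2, with log2 fold changes of −1.50 and −1.75 in the authors' deposited table, were named after their values were seen. Genes him-3, hil-4 and T12F5.2 are immediate neighbours of the targets pgl-1, pgl-3 and glh-4. Whether the RNAi acted on glh-2 directly, through sequence shared with a target, was not tested.

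The target list was the only list of 22 to pass at L4, with falls in 4 of 4 cases (4 adjusted over the list alone, Fisher exact BH-adjusted p = 9.35e-12, adjusted p = 0.000132 with an estimated correlation). In the germ granule list 1 of 44 genes fell (1 adjusted over the list alone), and in the meiotic prophase list 1 of 46 (1 adjusted over the list alone). No member of the spermatogenesis, oogenesis, stem cell or chromatin lists was called. A limma voom refit called 0 rises and 7 falls, with 979 genes at an unadjusted p below 0.05, but 96 rises and 556 falls without L4 RNAi library a and 206 and 597 with quality weights per library. In L4 RNAi libraries a, b and c, rol-6 of the hypodermis list stood at 417, 1.15 and 26.7 normalized reads. In L4 control libraries a, b and c it stood at 465, 142 and 163. By this gene RNAi library a was near control library a, and RNAi libraries b and c were below all controls. Any reads of the reporter transgene would also fall on rol-6. Soma-specific genes took 7.28, 4.47 and 4.65 percent of reads in these RNAi libraries, against 6.08, 5.097 and 5.44 percent in the controls. Whether differences in somatic tissue between libraries account for the few calls was not tested. Other splits of the same 6 libraries into 3 and 3 gave up to 1092 calls, where the real split gave 0 in a fit of these groups alone.

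The Day 1 comparison asks what differs in adult gonads that lack embryos. By list median, sperm genes rose most, with a median log2 fold change of 5.83 for major sperm protein genes in the authors' deposited table. The genes ssq-2 and ssq-4, members of a sperm-specific family, stood at 421 ± 232 and 419.6 ± 163 normalized reads against 0.2801 ± 0.485 and 1.01 ± 1.75 in controls (SD, n = 3 each). Genes msp-3, msp-57 and nspd-1 were at 241 ± 162, 209 ± 94.7 and 267 ± 165 (SD, n = 3), where controls were listed at 0. In the authors' deposited table, log2 fold changes were 7.55 for ssq-2, 6.62 for msp-40 and 7.02 for C04G2.8 (spch-1, a sperm chromatin protein gene). Their BH-adjusted p in the authors' deposited table were 2.13e-34, 2.27e-28 and 1.75e-35. Major sperm protein genes rose in 32 of 32 cases (32 adjusted over the list alone, Fisher exact BH-adjusted p = 2.04e-22, adjusted p = 0.112 with an estimated correlation). Rises among major sperm protein domain genes numbered 10 of 10 (10 adjusted over the list alone, Fisher exact BH-adjusted p = 3.65e-07, adjusted p = 0.112 with an estimated correlation). Spermatogenesis genes rose in 37 of 46 cases (38 adjusted over the list alone, Fisher exact BH-adjusted p = 6.83e-18, adjusted p = 0.112 with an estimated correlation). Members of these families are near copies and share reads. Of the authors' sperm category, 576 of 757 genes rose and 2 fell, and such a category is not independent evidence. Its reads made up 1.03, 2.30 and 1.00 percent of RNAi libraries a, b and c, against 0.188, 0.188 and 0.272 percent in controls.

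Germline genes fell at Day 1. Levels of oma-2, for an RNA-binding protein of oocyte maturation, were 978 ± 197 against 2195 ± 66.5, and those of prg-2, for a Piwi protein, 585 ± 103 against 1603 ± 176 (SD, n = 3 each). Ribonucleotide reductase gene rnr-1 was at 1274 ± 203 against 2428 ± 47.1, and cra-1, for a regulator of the synaptonemal complex, at 501 ± 14.5 against 953 ± 55.8 (SD, n = 3 each). Log2 fold changes in the authors' deposited table were −1.21 for oma-2, −1.47 for prg-2, −0.98 for rnr-1 and −0.99 for cra-1. The BH-adjusted p of these 4 genes in the authors' deposited table were 1.06e-12, 8.61e-18, 5.71e-10 and 1.43e-09. Germ granule genes fell in 26 of 44 cases (29 adjusted over the list alone, Fisher exact BH-adjusted p = 2.49e-14, adjusted p = 0.0534 with an estimated correlation). Oogenesis genes fell in 35 of 44 cases (37 adjusted over the list alone, Fisher exact BH-adjusted p = 1.51e-25, adjusted p = 0.23 with an estimated correlation). Falls in the meiotic prophase list numbered 24 of 47 (26 adjusted over the list alone, Fisher exact BH-adjusted p = 1.68e-11, adjusted p = 0.0765 with an estimated correlation). Stem cell genes fell in 22 of 30 cases (24 adjusted over the list alone, Fisher exact BH-adjusted p = 4.39e-15, adjusted p = 0.0805 with an estimated correlation). Chromatin regulators fell in 15 of 48 cases (18 adjusted over the list alone, Fisher exact BH-adjusted p = 0.000218, adjusted p = 0.209 with an estimated correlation). Among ribosomal protein genes, falls numbered 73 of 78 (74 adjusted over the list alone, Fisher exact BH-adjusted p = 1.4e-64, adjusted p = 0.317 with an estimated correlation). In that list rpl-12 was at 2482 ± 84.6 against 4729 ± 662, while rpl-25.1 rose, at 848 ± 278 against 32.95 ± 11.3 (SD, n = 3 each). The apoptosis list had falls in 7 of 29 cases (7 adjusted over the list alone, Fisher exact BH-adjusted p = 0.0494, adjusted p = 0.0765 with an estimated correlation). All RNAi targets fell, 4 of 4 (4 adjusted over the list alone, Fisher exact BH-adjusted p = 0.000363, adjusted p = 0.0133 with an estimated correlation).

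Genes of somatic tissues rose beside the sperm genes. Levels of let-2, for a collagen of basement membranes, were 4027 ± 714 against 329.7 ± 133, and of ost-1, for the matrix protein SPARC, 1054 ± 41.5 against 75.5 ± 30.3 (SD, n = 3 each). Muscle gene unc-22, for twitchin, was at 579 ± 179 against 122 ± 48.5, and cpr-4, for a cathepsin B of the intestine, at 377 ± 211 against 24.998 ± 10.03 (SD, n = 3 each). The neuronal gene casy-1, for calsyntenin, was at 236 ± 35.6 against 29.1 ± 5.19 (SD, n = 3 each). The authors' deposited table gave log2 fold changes of 3.52, 3.68, 2.13, 3.66 and 2.84 for these 5 genes. Their BH-adjusted p in the authors' deposited table were 3.99e-57, 1.5e-45, 4.54e-11, 8.24e-17 and 3.66e-18. Intestine genes rose in 31 of 45 cases (36 adjusted over the list alone, Fisher exact BH-adjusted p = 4.26e-12, adjusted p = 0.56 with an estimated correlation). Muscle genes rose in 25 of 49 cases (30 adjusted over the list alone, Fisher exact BH-adjusted p = 2.98e-06, adjusted p = 0.555 with an estimated correlation). Somatic gonad genes rose in 19 of 35 cases (19 adjusted over the list alone, Fisher exact BH-adjusted p = 1.81e-05, adjusted p = 0.336 with an estimated correlation). Histone genes rose in 26 of 71 cases (27 adjusted over the list alone, Fisher exact BH-adjusted p = 0.00187, adjusted p = 0.904 with an estimated correlation). Vitellogenins, yolk proteins made in the intestine, took 2.395, 7.43 and 8.85 percent of reads in RNAi libraries a, b and c, against 0.979, 1.72 and 1.92 percent in controls.

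Neuronal genes did not pass the list test at Day 1, with 17 of 53 higher (18 adjusted over the list alone, Fisher exact BH-adjusted p = 0.0562). No excess of calls passed for neuropeptides (1 higher and 0 lower of 21), hypodermis and seam (6 and 0 of 37) or cuticle collagens (10 and 0 of 75). Adjusted over the list alone, higher and lower genes in these 3 lists numbered 1 and 0, 5 and 0, and 6 and 0. Nor did an excess pass for developmental transcription factors (3 and 0 of 23), stress genes (9 and 8 of 40) or dosage compensation genes (0 and 1 of 19). Adjusted over the list alone these came to 2 and 0, 11 and 8, and 0 and 1. In all, 2505 genes rose and 1340 fell of 12910 tested in the authors' deposited table. The limma voom refit called 3861 genes, and 4710 without libraries c of both Day 1 groups. It called 2874 rises and 987 falls, but 1145 and 340, 1761 and 673, or 5632 and 1256 without Day 1 control library a, b or c, and 1908 and 401 without RNAi library b. With quality weights per group it called 1078 rises and 210 falls, and with weights per library 5355 and 1280.

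**Figure D2:**
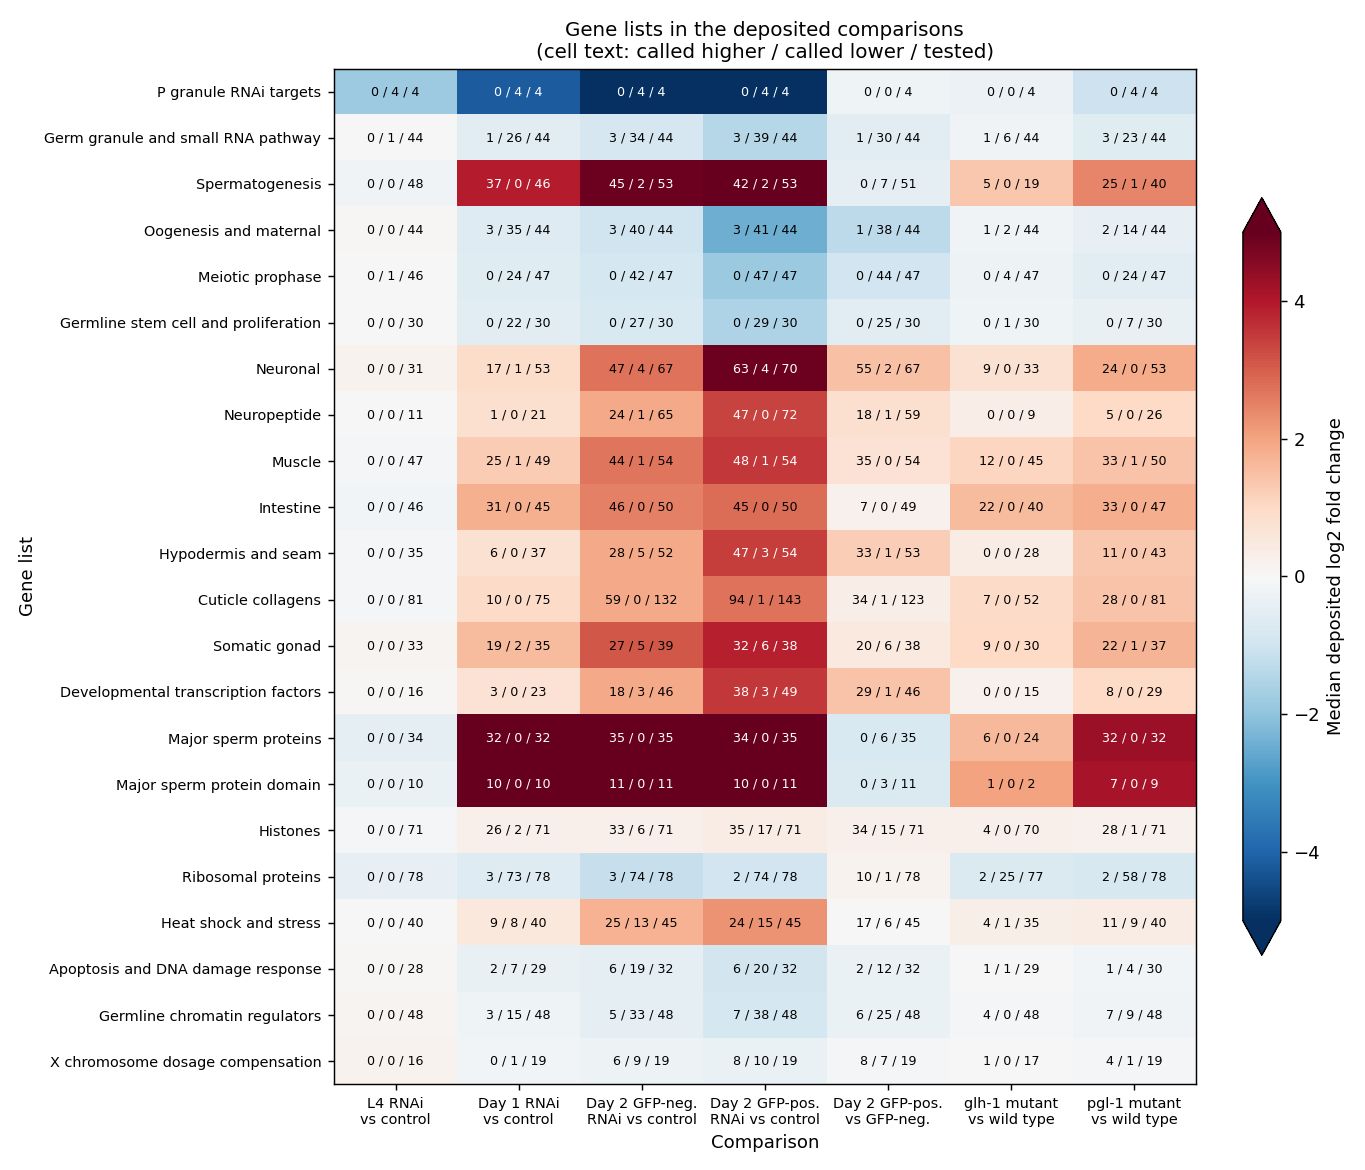
Median log2 fold change (colour, in the authors' deposited table) of 22 gene lists in 7 comparisons of gonads; each cell gives genes called higher, called lower and tested, and medians beyond the ends of the scale take its end colours. All 32 major sperm protein genes tested at Day 1 were called higher, and 73 of 78 ribosomal protein genes were called lower.

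The Day 2 comparison of GFP-negative RNAi gonads with controls asks whether the Day 1 pattern is met a day later in gonads without visible reporter. Sperm genes were again far above controls: gsp-3, for a sperm protein phosphatase, stood at 127 ± 6.23 against 0.141 ± 0.245, and fer-1, for a ferlin needed in sperm, at 144 ± 13.01 against 1.42 ± 0.374 (SD, n = 3 each). Germline helicase gene cgh-1 was at 4433 ± 455 against 13829.9 ± 168, and cey-2, for a Y-box protein, at 2437 ± 294 against 9074 ± 1208 (SD, n = 3 each). Muscle myosin gene unc-54 was at 2011 ± 128.6 against 205 ± 14.97, and casy-1 at 477 ± 91.2 against 27.5 ± 0.586 (SD, n = 3 each). Log2 fold changes of these 6 genes in the authors' deposited table were 8.05, 6.24, −1.82, −2.08, 3.09 and 3.90, with BH-adjusted p of at most 3.97e-21. Spermatogenesis genes rose in 45 of 53 cases (45 adjusted over the list alone, Fisher exact BH-adjusted p = 1.21e-11, adjusted p = 0.34 with an estimated correlation). Intestine genes rose in 46 of 50 cases (46 adjusted over the list alone, Fisher exact BH-adjusted p = 1.62e-14, adjusted p = 0.445 with an estimated correlation). Rises among muscle genes numbered 44 of 54 (44 adjusted over the list alone, Fisher exact BH-adjusted p = 3.3e-10, adjusted p = 0.34 with an estimated correlation). Neuronal genes rose in 47 of 67 cases (48 adjusted over the list alone, Fisher exact BH-adjusted p = 5.41e-07, adjusted p = 0.36 with an estimated correlation). Falls in the meiotic prophase list numbered 42 of 47 (43 adjusted over the list alone, Fisher exact BH-adjusted p = 7.85e-22, adjusted p = 0.0702 with an estimated correlation). Oogenesis genes fell in 40 of 44 cases (40 adjusted over the list alone, Fisher exact BH-adjusted p = 1.29e-21, adjusted p = 0.179 with an estimated correlation). Germ granule genes fell in 34 of 44 cases (35 adjusted over the list alone, Fisher exact BH-adjusted p = 2.67e-14, adjusted p = 0.0472 with an estimated correlation). Across all genes, 7185 rose and 4042 fell of 18817 tested in the authors' deposited table, and the median log2 fold change of those tested was 1.30.

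GFP-positive Day 2 gonads were compared with the same controls to ask what gonads with visible reporter hold. Of the genes taken by the naming rule, the 2 largest rises were those of sad-1, for a kinase of presynaptic sites, at 279.8 ± 85.97 against 0.166 ± 0.287, and egl-46, for a zinc finger protein of neurons, at 276 ± 49.4 against 0.166 ± 0.287 (SD, n = 3 each). From the neuronal list, unc-44, for an ankyrin, was at 5820.2 ± 1369 against 75.996 ± 4.38 (SD, n = 3 each). Epidermal gene noah-1, for an apical matrix protein, was at 583 ± 14.9 against 4.81 ± 1.72 (SD, n = 3 each). Chitin synthase gene chs-1, for the eggshell, was at 639 ± 87.5 against 4239.99 ± 413, and gld-3, for a Bicaudal-C protein, at 317 ± 47.2 against 1524 ± 158 (SD, n = 3 each). Log2 fold changes in the authors' deposited table were 9.27, 9.26, 5.78, 6.38, −3.19 and −2.72 for these 6 genes, with BH-adjusted p of at most 5.37e-21. Neuronal genes rose in 63 of 70 cases (64 adjusted over the list alone, Fisher exact BH-adjusted p = 6.17e-15, adjusted p = 0.256 with an estimated correlation). Rises among developmental transcription factors numbered 38 of 49 (39 adjusted over the list alone, Fisher exact BH-adjusted p = 6.57e-06, adjusted p = 0.411 with an estimated correlation). Hypodermis genes rose in 47 of 54 cases (47 adjusted over the list alone, Fisher exact BH-adjusted p = 2.91e-10, adjusted p = 0.557 with an estimated correlation). Rises among muscle genes numbered 48 of 54 (48 adjusted over the list alone, Fisher exact BH-adjusted p = 3.73e-11, adjusted p = 0.372 with an estimated correlation). Major sperm protein genes rose in 34 of 35 cases (34 adjusted over the list alone, Fisher exact BH-adjusted p = 6.69e-11, adjusted p = 0.506 with an estimated correlation). The meiotic prophase list fell as a whole, 47 of 47 (47 adjusted over the list alone, Fisher exact BH-adjusted p = 4.78e-29, adjusted p = 0.0451 with an estimated correlation). Oogenesis genes fell in 41 of 44 cases (41 adjusted over the list alone, Fisher exact BH-adjusted p = 1.22e-21, adjusted p = 0.178 with an estimated correlation). Falls in the germ granule list numbered 39 of 44 (39 adjusted over the list alone, Fisher exact BH-adjusted p = 8.21e-19, adjusted p = 0.0451 with an estimated correlation). The authors' deposited table held 9003 rises and 4770 falls among 20325 genes tested, with a median log2 fold change of 2.08 over them.

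The direct comparison of GFP-positive with GFP-negative Day 2 RNAi gonads asks what goes with visible reporter. Of the 6 largest rises taken by the naming rule, 4 were of cuticle collagen genes, with log2 fold changes of 5.34 (col-166), 5.06 (col-10), 4.85 (col-117) and 4.49 (col-3) in the authors' deposited table. Levels of col-166 were 114 ± 17.6 against 1.26 ± 0.846 (SD, n = 3 each). In the limma voom refit col-10, col-117 and col-3 did not pass (BH-adjusted p = 0.143, 0.159 and 0.160). Tubulin gene mec-7, also among these 6, and mec-12, from the neuronal list, were at 355 ± 40.6 and 277 ± 44.5 against 8.003 ± 4.23 and 11.8 ± 3.06 (SD, n = 3 each). Junction gene dlg-1 was at 836 ± 104.4 against 110.5 ± 29.7, and ztf-11, for a zinc finger protein of neuron formation, at 275 ± 61.96 against 38.5 ± 8.68 (SD, n = 3 each). Germline genes were lower than in GFP-negative gonads: egg-2, for a receptor on the egg surface, was at 145 ± 29.9 against 551 ± 44.1 (SD, n = 3 each). Synaptonemal complex gene syp-4 was at 183 ± 30.4 against 422 ± 28.5, and glp-1, for the Notch receptor of germline stem cells, at 769 ± 63.7 against 1341 ± 75.5 (SD, n = 3 each). In the authors' deposited table, log2 fold changes of mec-7, mec-12 and these 5 genes were 4.94, 4.14, 2.62, 2.51, −2.15, −1.44 and −1.05, with BH-adjusted p of at most 1.27e-13. Reporter gene unc-119 stood at 1035 ± 95.9 against 127 ± 45.5 (SD, n = 3 each), which is no finding, since the gonads were sorted by the reporter. No target differed in the authors' deposited table (log2 fold change 0.40 for pgl-1, BH-adjusted p = 0.671).

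Neuronal genes rose in 55 of 67 cases (55 adjusted over the list alone, Fisher exact BH-adjusted p = 4.62e-27, adjusted p = 0.144 with an estimated correlation) in that comparison. Rises among developmental transcription factors numbered 29 of 46 (33 adjusted over the list alone, Fisher exact BH-adjusted p = 5.62e-10, adjusted p = 0.276 with an estimated correlation). Hypodermis genes rose in 33 of 53 cases (33 adjusted over the list alone, Fisher exact BH-adjusted p = 5.39e-11, adjusted p = 0.472 with an estimated correlation). Rises among cuticle collagen genes numbered 34 of 123 (33 adjusted over the list alone, Fisher exact BH-adjusted p = 0.0435, adjusted p = 0.858 with an estimated correlation). As a whole the collagen list hardly differed, at 0.429 ± 0.0796 percent of reads in GFP-positive and 0.412 ± 0.132 percent in GFP-negative gonads (SD, n = 3 each). Muscle genes rose in 35 of 54 cases (36 adjusted over the list alone, Fisher exact BH-adjusted p = 3.09e-12, adjusted p = 0.307 with an estimated correlation). Falls in the meiotic prophase list numbered 44 of 47 (45 adjusted over the list alone, Fisher exact BH-adjusted p = 2.24e-27, adjusted p = 0.144 with an estimated correlation). Oogenesis genes fell in 38 of 44 cases (38 adjusted over the list alone, Fisher exact BH-adjusted p = 4.63e-21, adjusted p = 0.276 with an estimated correlation). Germ granule genes fell in 30 of 44 cases (32 adjusted over the list alone, Fisher exact BH-adjusted p = 5.89e-12, adjusted p = 0.144 with an estimated correlation). Genes of the authors' soma-specific category took 8.63, 7.64 and 7.66 percent of reads in GFP-positive and 5.07, 5.54 and 5.15 percent in GFP-negative libraries. In all, 3198 genes rose and 3072 fell of 16511 tested in the authors' deposited table. The limma voom refit called 3457 rises and 1438 falls, or 2265 and 950 without GFP-negative library a and 2537 and 827 without GFP-positive library a.

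**Figure D3:**
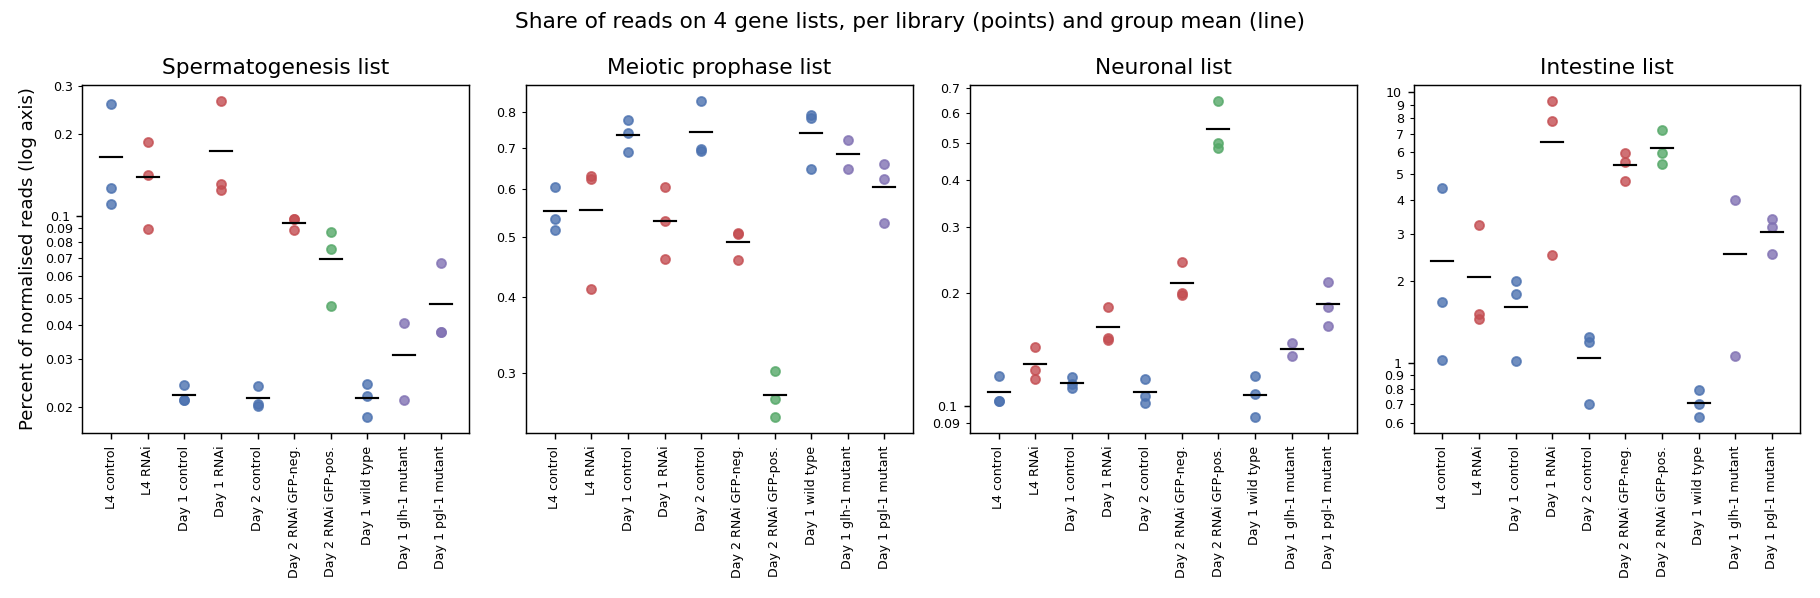
Percent of normalized reads (log axes) on 4 gene lists in 10 groups of gonads; points are libraries, lines are group means. The neuronal list held 0.544 percent of reads in GFP-positive and 0.212 percent in GFP-negative Day 2 RNAi gonads.

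Control gonads of Day 1 and L4 were compared to ask what differs between the stages, with a limma voom fit of the recovered reads. Sperm genes fell: msp-55 changed by a log2 difference of −7.30 ± 0.88 (SE, BH-adjusted p = 7.27e-05, limma voom), and msp-113 went from 147 ± 40.5 normalized reads (SD, n = 3) to a level listed at 0. Oocyte genes rose, with oma-2 at 2195 ± 66.5 against 900.3 ± 398 and egg-2 at 1221 ± 101 against 502 ± 203 (SD, n = 3 each). Their log2 differences were 1.61 ± 0.33 and 1.61 ± 0.32 (SE, BH-adjusted p = 0.00199 and 0.00167, limma voom). Cuticle collagen gene dpy-5 fell, at 1.01 ± 1.75 against 2166 ± 898, as did unc-27, for troponin I, at 73.8 ± 33.9 against 528 ± 43.04 (SD, n = 3 each). Fatty acid binding protein gene lbp-6 fell as well, at 48.97 ± 24.9 against 680.3 ± 221 (SD, n = 3 each). The cuticle collagen list took 1.99 percent of reads in L4 controls and 0.235 percent in Day 1 controls (group means). Falls of somatic genes therefore cannot be told apart from body wall tissue carried over at L4. Major sperm protein genes fell in 35 of 35 cases (35 in either direction adjusted over the list alone, camera adjusted p = 0.105 with an estimated correlation). Falls among spermatogenesis genes numbered 45 of 53 (49 in either direction adjusted over the list alone, camera adjusted p = 0.108 with an estimated correlation). Intestine genes fell in 35 of 51 cases (36 in either direction adjusted over the list alone, camera adjusted p = 0.332 with an estimated correlation). Muscle genes fell in 30 of 54 cases (42 in either direction adjusted over the list alone, camera adjusted p = 0.266 with an estimated correlation). Oogenesis genes rose in 35 of 44 cases (37 in either direction adjusted over the list alone, camera adjusted p = 0.105 with an estimated correlation). Rises among stem cell genes numbered 17 of 30 (24 in either direction adjusted over the list alone, camera adjusted p = 0.105 with an estimated correlation). The fit called 1283 rises and 3620 falls, or 64 and 1743 without L4 control library a, 389 and 1594 without Day 1 control library a, and 1485 and 5450 without library c of the latter.

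Between Day 2 and Day 1 controls the same fit called 1 rise and 1 fall, with 3412 genes at an unadjusted p below 0.05. The rise was Y24D9A.9, at 5007 ± 379 against 2536 ± 173 (SD, n = 3 each), with a log2 difference of 1.03 ± 0.16 (SE, BH-adjusted p = 0.034, limma voom). The fall was C26H9A.2, at 83.04 ± 10.3 against 361 ± 27.1 (SD, n = 3 each), with −2.09 ± 0.25 (SE, BH-adjusted p = 0.00212, limma voom). The count was 100 without Day 2 control library c, 5 and 7 without a or b, and 1 without any Day 1 control library. Other splits of these libraries gave up to 461 calls, against 24 for the real split in a fit of these groups alone.

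How far the RNAi effect differed between Day 1 and L4 was tested as an interaction. Day 1 RNAi gonads came from sterile worms, while L4 RNAi gonads were taken before sterility could be seen. A difference between the stages cannot be told apart from this selection. Sperm gene ssq-2 was at 421 ± 232 against 0.2801 ± 0.485 in RNAi and control gonads at Day 1, and at 291 ± 77.7 against 482 ± 46.5 at L4 (SD, n = 3 each). Its log2 difference of effects was 9.56 ± 1.68 (SE, BH-adjusted p = 0.00236, limma voom), and that of msp-55 was 8.01 ± 0.96 (SE, BH-adjusted p = 0.000293, limma voom). The somatic gonad gene ost-1 was at 1054 ± 41.5 against 75.5 ± 30.3 at Day 1 and at 986 ± 596 against 817 ± 133 at L4 (SD, n = 3 each). Its difference was 3.86 ± 0.64 (SE, BH-adjusted p = 0.00165, limma voom). A lower effect at Day 1 was met for csr-1, for an Argonaute of P granules, at 1499.7 ± 203 against 2914 ± 99.7 at Day 1 and 2291 ± 101 against 2816 ± 174 at L4 (SD, n = 3 each). Its difference was −0.61 ± 0.13 (SE, BH-adjusted p = 0.00848, limma voom). Major sperm protein genes had a higher effect at Day 1 in 34 of 35 cases (35 in either direction adjusted over the list alone, camera adjusted p = 0.0682 with an estimated correlation). Spermatogenesis genes did so in 36 of 53 cases (45 in either direction adjusted over the list alone, camera adjusted p = 0.0779 with an estimated correlation). Among muscle genes it was 4 of 54 (18 in either direction adjusted over the list alone, camera adjusted p = 0.528 with an estimated correlation). In total 1045 genes had a higher and 33 a lower effect at Day 1. The total of 1078 became 459 (1 of them lower) without L4 control library a and 3772 (3084 higher and 688 lower) without L4 RNAi library a. It became 382, 593 and 2737 without Day 1 control library a, b or c, 1788 and 659 without Day 1 RNAi library a or b, and 2159 without both Day 1 libraries c. Genes with a lower effect numbered 7, 20 and 89 without Day 1 control library a, b or c, 73 and 12 without Day 1 RNAi library a or b, and 13 and 21 without L4 RNAi library b or c.

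Between Day 2 GFP-negative and Day 1 RNAi effects 1 gene passed, with 1606 at an unadjusted p below 0.05. Argonaute gene ppw-2 was at 1242 ± 117.2 against 2207 ± 48.2 at Day 2 and 1762 ± 155 against 2021 ± 166 at Day 1 (SD, n = 3 each). Its difference was −0.74 ± 0.11 (SE, BH-adjusted p = 0.0464, limma voom). The count fell to 0 without any of the Day 1 libraries or Day 2 control library b or GFP-negative library a or b, and 50 and 3 genes passed without Day 2 control library c or a.

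Day 1 gonads of the glh-1 mutant were compared with wild type to ask what differs in a strain with a deletion in 1 helicase gene. Of the genes taken by the naming rule the largest rise was again that of glit-1, at 1162 ± 67.7 (SD, n = 2) against 26.8 ± 21.3 (SD, n = 3). Levels of rpl-25.1 were 589.8 ± 473 against 9.95 ± 4.44, and those of puf-9, for a Pumilio-family protein, 862 ± 51.7 against 58.5 ± 28.9 (SD, n = 2 and 3). The largest fall among them was that of gln-6, a glutamine synthetase gene, at 38.4 ± 0.296 against 1921 ± 89.3 (SD, n = 2 and 3). P granule gene deps-1 was at 469 ± 207 against 1141 ± 114 (SD, n = 2 and 3). The authors' deposited table gave log2 fold changes of 5.06, 4.98, 3.71, −5.44 and −1.22 for these 5 genes, with BH-adjusted p of at most 0.000801. Intestine genes rose in 22 of 40 cases (34 adjusted over the list alone, Fisher exact BH-adjusted p = 7.85e-15, adjusted p = 0.304 with an estimated correlation). The list took 1.06 and 3.99 percent of reads in glh-1 libraries a and b, against 0.628, 0.702 and 0.793 percent in wild type, and vitellogenins took 0.9751 and 3.79 percent in glh-1 libraries a and b. In that list lys-8, a lysozyme gene, rose by a log2 fold change of 2.46 in the authors' deposited table (BH-adjusted p = 3.3e-06). Muscle genes rose in 12 of 45 cases (18 adjusted over the list alone, Fisher exact BH-adjusted p = 0.000388, adjusted p = 0.35 with an estimated correlation). Somatic gonad genes rose in 9 of 30 cases (11 adjusted over the list alone, Fisher exact BH-adjusted p = 0.0011, adjusted p = 0.304 with an estimated correlation). Rises among neuronal genes numbered 9 of 33 (11 adjusted over the list alone, Fisher exact BH-adjusted p = 0.00198, adjusted p = 0.324 with an estimated correlation). Major sperm protein genes rose in 6 of 24 cases (24 adjusted over the list alone, Fisher exact BH-adjusted p = 0.026, adjusted p = 0.341 with an estimated correlation). Ribosomal protein genes fell in 25 of 77 cases (55 adjusted over the list alone, Fisher exact BH-adjusted p = 3.07e-20, adjusted p = 0.304 with an estimated correlation). Falls in the germ granule list numbered 6 of 44 (6 adjusted over the list alone, Fisher exact BH-adjusted p = 0.00503, adjusted p = 0.304 with an estimated correlation). The authors' deposited table held 649 rises and 240 falls among 9718 genes tested. The limma voom refit called 816 rises and 231 falls, but 142 and 59 without wild-type library a, 256 and 89 without wild-type library b, and 607 and 19 without glh-1 library a.

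The pgl-1 mutant was compared with the same wild-type gonads. Here too glit-1 and rpl-25.1 were far above wild type, at 1885 ± 288 and 1013 ± 428 against 26.8 ± 21.3 and 9.95 ± 4.44 (SD, n = 3 each). P granule gene deps-1 was at 111 ± 20.1 against 1141 ± 114, and pgl-3 at 550.002 ± 72.5 against 1264 ± 363 (SD, n = 3 each). Meiotic crossover gene msh-5 was at 205 ± 16.16 against 434 ± 36.1 (SD, n = 3 each). Yolk protein gene vit-5 was at 12563 ± 1668 against 3011 ± 341 and fer-1 at 42.99 ± 24.9 against 0.534 ± 0.494 (SD, n = 3 each). Log2 fold changes of 6 of these genes (all but pgl-3) were 6.09, 6.39, −3.31, −1.07, 2.04 and 4.72 in the authors' deposited table. Their BH-adjusted p in the authors' deposited table were at most 2.49e-07, and that of pgl-3 was 1.45e-05. Major sperm protein genes rose in 32 of 32 cases (32 adjusted over the list alone, Fisher exact BH-adjusted p = 2.52e-20, adjusted p = 0.284 with an estimated correlation). Intestine genes rose in 33 of 47 cases (33 adjusted over the list alone, Fisher exact BH-adjusted p = 2.62e-11, adjusted p = 0.242 with an estimated correlation). Muscle genes rose in 33 of 50 cases (36 adjusted over the list alone, Fisher exact BH-adjusted p = 3.06e-10, adjusted p = 0.242 with an estimated correlation). Rises among neuronal genes numbered 24 of 53 (30 adjusted over the list alone, Fisher exact BH-adjusted p = 0.000639, adjusted p = 0.129 with an estimated correlation). Ribosomal protein genes fell in 58 of 78 cases (60 adjusted over the list alone, Fisher exact BH-adjusted p = 3.22e-43, adjusted p = 0.202 with an estimated correlation). Falls in the meiotic prophase list numbered 24 of 47 (29 adjusted over the list alone, Fisher exact BH-adjusted p = 1.33e-12, adjusted p = 0.129 with an estimated correlation). Germ granule genes fell in 23 of 44 cases (26 adjusted over the list alone, Fisher exact BH-adjusted p = 1.71e-12, adjusted p = 0.129 with an estimated correlation). The strain also carries a him-3 allele, so effects of pgl-1 and him-3 cannot be set apart here. The authors' deposited table held 2997 rises and 1190 falls among 13469 genes tested. The limma voom refit called 3640 rises and 1295 falls, or 1718 and 737 without wild-type library a, 2270 and 874 without wild-type library b, and 2612 and 673 without pgl-1 library a.

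Calls were compared between comparisons that share no library. Of the 2505 genes that rose at Day 1, 2451 rose in Day 2 GFP-negative gonads, where 1114 would be shared by independent lists, and 1332 of the 1340 that fell also fell (419). With the pgl-1 mutant, the Day 1 RNAi effect shared 1608 rises (546) and 694 falls (132), and with the glh-1 mutant 532 rises (111) and 166 falls (33.4). All 13 genes that rose at L4 rose at Day 1 (2.90), among them glit-1, and 8 of the 9 that fell at L4 fell at Day 1 (1.14). Those 8 were the RNAi targets, their neighbours him-3, hil-4 and T12F5.2, and glh-2. The targets were lowered by the RNAi at both stages, so the value of 1.14 tests nothing for these falls. The remaining gene, hacd-1, was at 42.7 ± 12.9 against 195 ± 67.4 at L4. At Day 1 it was higher in RNAi gonads, at 143 ± 92.2 against 17.6 ± 2.14 (SD, n = 3 each).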

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

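All tests of explanations in this part, the splits included, were chosen after the results were seen, except that of larval transcripts persisting. That exception was predicted before its value was computed. The interaction comparisons, fits of the compared groups alone and the leaving out of single libraries were planned, though the voom fit was not. The RNAi effect differed between Day 1 and L4 in 1078 genes by the interaction test, 1045 of them with a higher effect at Day 1, and 538 of these in the authors' sperm category. In 100 splits, the real one was counted and the others regrouped the stages within control and within RNAi libraries. Of these, 12 gave at least as many calls as the real one, itself included (504 in a fit of these groups alone, highest other 5177). Of 10 that kept the control but not the RNAi stages apart, and so carried the stage difference, 7 reached that count, as did 1 that kept both with 1 of them reversed (3158) and 0 of 13 that kept the RNAi stages alone apart (highest 50), so the share does not tell whether chance is excluded. The highest came from the 75 that kept neither stage grouping, of which 3 reached the count; it points to a structure of the libraries, and which one was not tested. Between Day 2 GFP-negative and Day 1 gonads, 1 gene, ppw-2, was called by the interaction test, and the call was lost without most single libraries. Here 4 of 100 such splits, the real one included, gave at least the real count of 9 in a fit of these groups alone (highest other 64). Regrouping the stages also puts their difference into the spread, so this share does not tell whether chance is excluded either.

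Sperm transcripts in adult RNAi gonads were weighed first. A lower germline share that raises other cell types alike would lift sperm and somatic genes alike only if the rest of the germline added few of their reads. At Day 1 the median log2 fold change in the authors' deposited table was higher by 1.78 for sperm than for soma-specific genes (95% bootstrap interval 1.60 to 1.93, medians 2.84 and 1.06). Bootstrap intervals in this part resampled genes as if independent, with the libraries fixed, so they hold no spread between libraries. In Day 1 control libraries a, b and c, soma-specific genes already took 4.09, 4.00 and 4.30 percent of reads, and sperm genes 0.188, 0.188 and 0.272 percent. Germline reads in the soma-specific category would limit its rise, so the difference does not decide on that explanation. Whole stunted gonads, taken with proximal parts and perhaps sheath and spermatheca, may add such reads: 19 of 35 somatic gonad genes rose, and because which gonads were taken whole went with the RNAi, this cannot be told apart from a change in the germline. Larval transcripts that persist in adults may also take part: outside the sperm category, genes that fell from L4 to Day 1 in controls rose in Day 2 GFP-negative RNAi gonads with an odds ratio of 8.02 against other genes (2156 of 2814, against 4308 of 14855), and of 2.81, 7.86 and 14.4 at low, middle and high expression. That prediction was met, but genes falling from L4 include collagens and genes of muscle and intestine, so the test does not separate persisting germline transcripts from somatic tissue.

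Neuronal transcripts in GFP-positive gonads were weighed next. Reads of the reporter transgene would touch unc-119 and rol-6 alone, whereas 55 of 67 neuronal genes other than these rose over GFP-negative gonads, which argues against them. A lower germline share that raises other cell types alike would lift neuronal and intestine genes alike only if germ cells added few of their reads. The difference of their median log2 fold changes in the authors' deposited table was 1.26 (95% bootstrap interval 1.00 to 1.74, medians 1.48 and 0.22). The 2 lists thus did not rise alike. How many reads germ cells add to each list was not measured, so this does not decide on that explanation. Carry-over of body wall tissue with its neurons may add reads: 35 of 54 muscle genes rose as well, and tissue carried over cannot be told apart from transcripts made in the gonad.

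The genes next to the RNAi targets were weighed last. At L4, 3 of 6 tested neighbours fell (him-3, hil-4 and T12F5.2), against 2 of 10914 other genes (two-sided Fisher exact test, p = 9.21e-10), but neighbours were looked at because these falls had been seen, so this p does not test chance. Reads shared with the target gene may account for it, but the ratio of the him-3 to the pgl-1 change in the pgl-1 mutant, 0.195, cannot be told apart from an effect of the him-3 allele in that strain. A general loss of germline transcripts as deep as that of him-3 would lower the meiotic prophase list alike. The list's median log2 fold change in the authors' deposited table was −0.031 (95% bootstrap interval −0.08 to 0.02). Deposited fold changes at L4 can understate a change. Summed normalized reads of the list were 20198 ± 3500 in L4 RNAi and 21895 ± 1651 in L4 control gonads (SD, n = 3 each). These values argue against a loss of that depth, while a small one is not excluded.

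In a fit of the compared groups alone, the real split of the L4 libraries gave 0 calls (highest other 1092). Any split reaches 0, so the share of 10 of 10 tests nothing. Of 10 splits of the Day 2 and Day 1 control libraries, 4 gave at least the real 24 (highest other 461). In 1 of 10 splits, the real one, the calls were 3863 for Day 1 RNAi, 12367 for Day 2 GFP-negative, 15378 for Day 2 GFP-positive, 7008 for GFP-positive against GFP-negative, 5846 for Day 1 against L4 control and 4939 for the pgl-1 mutant, with a highest other of 0 in each; 10 splits are too few for a share under 0.05.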

How the results depend on the processing

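Of the alternatives in this part, the voom fit, the weights, the libraries c left out together and the centring were chosen after the results were seen. No paired analysis was possible because the recovered libraries carry no replicate number. For named genes, 330 of 340 changes in the authors' deposited table kept their direction and side of the threshold at an adjusted p of 0.01 and 317 with limma voom. In GFP-positive against GFP-negative gonads pgl-1 turned from 0.40 to −0.13 and glh-1 from −0.12 to 0.29 with voom, none of these a call. Most named genes were chosen for a small p or a large change without overlap of these libraries, so they do not measure agreement over all calls. Of all deposited calls, voom shared 0 of 13 rises and 7 of 9 falls at L4, and 1984 of 2505 and 898 of 1340 at Day 1. It shared 2744 of 3198 rises and 1427 of 3072 falls for GFP-positive against GFP-negative gonads, and 2909 of 2997 and 1117 of 1190 for pgl-1. At an adjusted p of 0.01 the calls were 14 at L4, 2530 at Day 1 (1747 rises, 783 falls), 466 for glh-1 (364, 102) and 2587 for pgl-1 (1979, 608). With a fold of at least 2 they were 2510 at Day 1 (2383 rises, 127 falls) and 2960 for GFP-positive against GFP-negative gonads (2268, 692). That setting took falls to 965 in Day 2 GFP-negative, 3049 in Day 2 GFP-positive, 110 in glh-1 and 273 in pgl-1 gonads, and rises to 6833, 8777, 626 and 2894; both settings keep fewer genes by construction. At L4 voom gave 7 calls, 0 with the compared groups alone, and 9 and 803 with weights per group and per library. There limma-trend gave 117, 174 and 92 at pseudocounts 1, 0.1 and 5, and 27 and 654 (320 rises, 334 falls) with weights per group and per library. Day 1 RNAi had 1288 and 6635 calls with voom weights per group and per library, and 1717 (1540 rises, 177 falls) and 6832 with limma-trend weights. For GFP-positive against GFP-negative gonads limma-trend gave 2819, 2030 and 3823 at those pseudocounts, and voom 7243 and 7443 with weights per group and per library. Day 2 GFP-negative had 7043 with limma-trend at pseudocount 5. The glh-1 comparison had 611 at that pseudocount, 689 and 1611 with limma-trend weights per group and per library, and 1434 with voom weights per library; pgl-1 had 7365 with limma-trend weights per library. Day 1 against L4 control had 7494 calls (2528 rises, 4966 falls) with limma-trend weights per library and 15754 (2440, 13314) with voom weights per library. Day 2 against Day 1 control had 6, 17 and 6 calls with limma-trend at pseudocounts 1, 0.1 and 5, 24 with the compared groups alone, 634 with limma-trend weights per library, 1 and 102 with voom weights per group and per library, and 1 without Day 1 libraries c. The Day 1 to L4 difference had 1920 and 1890 at pseudocounts 1 and 0.1, 504 with the compared groups alone, 4199 (704 lower) with limma-trend weights per library, 401 and 5070 (2 and 562 lower) with voom weights per group and per library, and 2159 without Day 1 libraries c. The Day 2 to Day 1 difference had 7, 6 and 7 at pseudocounts 1, 0.1 and 5, 9 with the compared groups alone, 2 and 236 with limma-trend weights per group and per library, 0 and 9 with voom weights per group and per library, and 0 without Day 1 libraries c. Leaving out 1 library at a time gave 7 to 652 voom calls at L4, 1485 to 6888 at Day 1, 8923 to 9893 for Day 2 GFP-negative, 13096 to 13978 for Day 2 GFP-positive, 3215 to 4498 for GFP-positive against GFP-negative, 201 to 895 for glh-1, 2455 to 5143 for pgl-1, 1807 to 6935 for Day 1 against L4 control, 1 to 100 for Day 2 against Day 1 control, 382 to 3772 for the Day 1 to L4 difference and 0 to 50 for the Day 2 to Day 1 difference; a group left with 1 library is assumed to vary like the others. Of list tests 105 passed, counting lists with fewer calls than other genes, against 6 for camera with an estimated correlation, 83 with fry directional, 115 with fry mixed and 77 without lists made by name prefix. Fry asks whether a list changed at all, not whether it changed more than other genes, so its counts answer another question. At an adjusted p of 0.01 the shared calls were 778 falls (Day 1 and Day 2 GFP-negative), 774 falls (Day 1 and Day 2 GFP-positive), 283 rises and 59 falls (Day 1 and glh-1), 997 rises and 325 falls (Day 1 and pgl-1), 1867 rises and 591 falls (Day 2 GFP-negative and pgl-1), 5 rises (L4 and Day 1), and 3 rises and 2 falls (L4 and pgl-1). Except where fewer genes or libraries show it, the cause was not tested. Centring on the authors' ubiquitous genes, whose median log2 fold change in the authors' deposited table was −0.51 in Day 2 GFP-positive gonads, turned 9003 rises there into 9260. Count tools other than limma, a replicate block and split controls were planned and not run. Depth limits low genes most, since the shallowest library holds 1027223 reads.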

Other observations

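No hypothesis was tested in this part, and its genes were grouped after the results were seen. Ribosomal protein genes moved in opposite directions. At Day 1 and in both mutants this list did not pass camera with an estimated correlation. While 74 of 78 fell in Day 2 GFP-negative gonads (74 adjusted over the list alone), rpl-25.1 and rpl-11.2 rose: rpl-11.2 stood at 1281 ± 115.8 against 70.4 ± 19.2 in Day 2 GFP-negative gonads, and at 2221 ± 820.01 in the pgl-1 mutant against 62.1 ± 39.9 in wild type (SD, n = 3 each). The authors' deposited table gave rpl-11.2 log2 fold changes of 3.97, 5.31, 3.42 and 4.94 in Day 2 GFP-negative, Day 2 GFP-positive, glh-1 and pgl-1 gonads, with BH-adjusted p of 3.34e-93, 1.79e-159, 1.13e-14 and 3.59e-36. Both genes fell from L4 to Day 1 in control gonads (log2 differences −4.29 ± 0.75 for rpl-25.1 and −3.84 ± 0.64 for rpl-11.2 (SE), BH-adjusted p = 0.000773 and 0.000578, limma voom).

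Stress genes moved in both directions. In GFP-positive Day 2 gonads the HSP70 family genes F44E5.4 and F44E5.5, which lie side by side and share sequence, stood at 381 ± 103.95 and 385 ± 81.5 against 2.09 ± 0.396 and 2.23 ± 0.221 (SD, n = 3 each), while 24 of 45 stress genes were called higher and 15 lower in that comparison (24 and 15 adjusted over the list alone). The caspase gene ced-3 was lower in these gonads by a log2 fold change of −1.56 in the authors' deposited table (BH-adjusted p = 7.83e-40). F-box gene fbxa-192 fell in both mutants, by log2 fold changes of −4.25 in glh-1 and −3.49 in pgl-1 gonads in the authors' deposited table (BH-adjusted p = 3.8e-22 and 2.58e-18).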
